A study of Mus musculus with 4 samples.

How the data were processed

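Total RNA of 4 mouse cerebellar tumors, 1 array per tumor, was measured on the Affymetrix Mouse Genome 430 2.0 array, on which a transcript is read by a probe set of short oligonucleotides. The sample titles give the genotype Chd7-het and the numbers 1, 2, 4 and 5, which serve here as names of the tumors, and the labels give a mixed CD1xC57BL/6 background. Per the labels' protocols, RNA was taken from milled frozen tissue with TRIzol and cleaned on a spin column. The labels put every tumor in a single group, with no normal cerebellum and no tumor of another genotype, so no groups were compared. They give neither sex nor age of the mice.

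The deposited values are log2 signals, and the submitters' processing notes name MAS5, the Affymetrix method that summarizes a probe set on its own array and scales arrays to a common level. Its version and scaling target are not given in the sources used here. Back on the linear scale, 100% of the deposited values fell on steps of 0.1, to within 0.0001, and the lowest was 1. The table used here held 29304 probe sets, which is part of the array's design, and no detection calls, so whether a transcript was present had to be judged from its signal. MAS5 subtracts a local background, which makes low signals noisy on the log scale. It does not align the distributions of the arrays, so signal-dependent differences between arrays can remain.

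Probe sets were named through the platform annotation supplied with the series. A single gene symbol was given for 24679 probe sets, several for 647 and none for 3917, and 61 probe sets were Affymetrix controls. No gene was named from a probe set with several symbols. Of the probe sets with a single symbol, 24614 were found by gene identifier in the RefSeq gene table of the GRCm38.p6 assembly, which was used to see which genes lie on the same chromosome or next to each other. No coordinates are given, since the annotation behind the deposited values names no build.

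The settings, the tests, the rule for named genes and 26 gene lists were fixed before the data were examined. The log2 values were used as deposited. Signals were raised to a common floor, the median over arrays of each array's 40th percentile, which was 5.12 on the log2 scale or 34.8 linear. A probe set was kept if its mean over the 4 tumors was at or above the median of all means, 5.87 on the log2 scale or 58.5 linear. Of the 13525 probe sets kept with a single gene, the one with the highest mean stood for its gene, which left 8498 genes, of which 8464 lay above the floor in all 4 tumors. A mean filter removes genes that are high in a single tumor and low in the rest, so such genes were looked at separately. Where the values at the floor all lie on the lower side of a difference, its size is a lower bound, and single genes of this kind are written "at least" or said to be at the floor. Where a tumor lies between floored and higher tumors, raising values to the floor can enlarge a negative difference or turn a positive one negative, so a list median that holds such genes is no bound.

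Each tumor in turn was set against the other 3 with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes and a difference of 2-fold or more. The lone tumor is assumed in this fit to vary like the other 3, so the test asks whether it lies outside their spread and says nothing about a population of tumors. The 4 fits share tumors, and a tumor far from the rest widens the spread in the other 3 fits. When a tumor is left out as well, a gene can pass though the lone tumor lies between the remaining ones. Counts of passing genes from those fits therefore do not show a tumor outside the rest. The arrays are of separate tumors, and nothing used here says whether a number also marks a separate litter or batch.

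For each list, the median over its genes of the tumor's log2 signal minus the mean of the other 3 was ranked among 10000 random lists of the same size, matched on mean signal in 20 bins. A list was called apart at or under the percentile 0.5 or at or over 99.5, and lists with fewer than 5 genes past the filter got values without a test. This percentile describes these arrays and treats genes as independent. Random lists can themselves have a median away from no difference. Counts of members higher or lower do not allow for this and include any shift shared by genes of like signal. Because genes of a list vary together, the limma function camera was run with an estimated correlation, and with its preset correlation of 0.01, as alternatives. That estimate rests on the few residuals left by a single tumor against the other 3, so it could hardly call any list. A shift whose call it did not keep is therefore not shown to be absent. The term camera adjusted p stands for its adjusted p with an estimated correlation, with all 4 tumors. The spread of a list was the SD over the tumors of its mean deviation, ranked in the same way.

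The lists cover sonic hedgehog (SHH) and WNT signaling, photoreceptor and group 3 or 4 medulloblastoma markers, granule cell progenitors, mature neurons, Purkinje cells and inhibitory neurons, astrocytes and Bergmann glia, oligodendrocytes, microglia and macrophages, lymphocytes, endothelial cells, fibroblasts with meninges and mural cells, choroid plexus, ciliated cells, erythroid cells, skeletal muscle, S phase, G2 and M phase, p53 targets, interferon response, hypoxia, immediate early genes, heat shock proteins, CHD remodellers, imprinted genes, and MYC and ribosome biogenesis targets.

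Named genes were Chd7, per tumor up to 6 passing genes with the largest differences among those above the floor in all tumors (the 3 largest differences as values where fewer than 3 passed), the 10 genes with the largest SD, up to 6 genes at the floor in some tumors and 4-fold or more above it in another, Xist and Y-linked genes, the 3 leading members of each list called apart, and 12 genes known from medulloblastoma. The Y-linked gene Ddx3y was not analysed here. Genes chosen after their values were seen are marked as such.

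Alternatives were quantile normalization, median centring, floors at the 25th and 50th percentiles, no mean filter, a filter at the 75th percentile, log2 of signal plus the floor value in place of a floor, the mean of all probe sets of a gene, leaving out probe sets with an _x_at or _s_at suffix, other variance models, adjusted p without a fold threshold, and leaving out each tumor in turn. A split of the samples into other groups of the same sizes was not applicable, since each comparison has a single tumor on one side.

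The tests were tried on simulated data. For tumor 1 against the other 3 over 8498 genes, 63% of 100 genes given a log2 change of 1.5 and 93% of 100 genes given a change of 3 were recovered, with 1 false call. For the list test, a list of 15 genes shifted by 0.5 reached the percentile 100, and 0 of 200 unshifted comparisons were called.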

Results

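Gene expression was measured in 4 mouse cerebellar tumors with the genotype Chd7-het, called tumors 1, 2, 4 and 5 after their sample numbers, with 1 array per tumor. Chd7 encodes a chromatin remodelling ATPase. Between 59.1% and 61.3% of the probe sets lay above the floor on each array (17912, 17789, 17314 and 17271 probe sets in tumors 1, 2, 4 and 5). The ratio of the 3' to the 5' Gapdh control probe set, a sign of RNA quality, lay between 0.686 and 0.757, and that of the actin control between 1.11 and 1.17. The number of arrays limits the precision of every value.

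Chd7 lay above the floor in every tumor. Its brighter probe set, 1448026_at, read 8.77, 8.66, 8.48 and 8.60 on the log2 scale in tumors 1, 2, 4 and 5 (mean 8.63 ± 0.12, SD, n = 4), and the other, 1437745_at, read 7.43, 7.29, 6.85 and 6.96 (7.13 ± 0.27, SD, n = 4). No tumor of another genotype was among the samples, so these levels check no label and no effect of the genotype could be measured.

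Genes known from medulloblastoma subgroups were then read in the 4 tumors. Members of the SHH pathway, which drives the division of granule cell progenitors, lay above the floor throughout: Ptch1, the SHH receptor, at 11.14 ± 0.12, Gli1, a transcription factor and pathway target, at 7.44 ± 0.30, Hhip at 6.14 ± 0.43 and Sfrp1 at 10.56 ± 0.31 (log2 signal, SD, n = 4 here and below). Atoh1, the transcription factor of granule cell progenitors, read 10.54 ± 0.44, the cyclin gene Ccnd1 10.55 ± 0.21 and the proliferation marker Mki67 10.16 ± 0.40, and Mycn, an SHH-responsive MYC family gene, read 10.82, 10.88, 11.13 and 11.17 in tumors 1, 2, 4 and 5. Of the WNT target genes, Lef1 lay below the floor in all 4 tumors (3.62 ± 0.18), and Axin2 lay above it (5.92 ± 0.12). Otx2 read 9.28 ± 0.14 and Myc 8.14 ± 0.29. These are levels of single probe sets, and levels of different genes were not compared.

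The tumors were next compared with each other over 8498 genes. Tumor 1 stood farthest from the rest. It differed by 2-fold or more in 214, 208 and 266 genes from tumors 2, 4 and 5, whereas tumors 2 and 4 differed in 36 genes, tumors 4 and 5 in 39 and tumors 2 and 5 in 108. Pearson's r across genes, which are not independent replicates, was between 0.948 and 0.958 for the pairs with tumor 1 and between 0.964 and 0.984 for the others. The first principal component held 54.3% of the variance, with a weight of 0.84 for tumor 1 and of -0.11, -0.29 and -0.44 for tumors 2, 4 and 5. The B1 repeat control probe set also read highest on array 1, at 10.97, and between 9.24 and 9.82 on the others.

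In tumor 1, transcripts of differentiated cerebellar neurons and of myelin were higher than in the other tumors, and Lcn2 was lower. Calb1, the calcium-binding protein calbindin of Purkinje cells, was at least 16.3-fold higher, and Gad1, the enzyme that makes GABA, at least 10.8-fold. Car8, a Purkinje cell protein, was 8.93-fold higher (log2 difference 3.16, SE 0.32, adjusted p = 0.00411), Cadps2, which acts in the release of dense-core vesicles, 9.13-fold (3.19, SE 0.20, adjusted p = 0.000942), and the neuronal adhesion molecule gene L1cam 7.79-fold (2.96, SE 0.30, adjusted p = 0.00374). Mbp, which encodes myelin basic protein, was 7.78-fold higher (2.96, SE 0.49, adjusted p = 0.0282) and Calb2, the calretinin gene, 6.83-fold (2.77, SE 0.29, adjusted p = 0.00411). Lcn2, which encodes the iron-siderophore-binding protein lipocalin 2, differed by -3.97 (SE 0.38, adjusted p = 0.00307), with a signal of 5.48 in tumor 1 and 9.44 ± 0.63 in the other 3 (SD, n = 3).

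In total, 110 genes in tumor 1 lay outside the spread of the other 3 in the limma test, 89 higher and 21 lower. Of the 26 of them with another probe set past the filter, 26 had that probe set on the same side, 18 by 2-fold or more. Of the 8 probe sets of Mbp, 2 did not follow the others: 1425263_a_at read 6.24 in tumor 1 and between 6.15 and 6.49 in the rest, and 1425264_s_at 7.61 and 7.65 in tumors 1 and 2, with tumor 4 at 7.52 and tumor 5 higher. With no filter on the mean, Lcn2 (adjusted p = 0.178), Car8 (0.177), L1cam (0.152), Mbp (0.393) and Calb2 (0.127) no longer passed and Cadps2 did (0.0134). Mbp also lost its call with the floor at the 50th percentile (adjusted p = 0.112), where 57 genes passed in tumor 1, and 29 passed with the mean filter at the 75th percentile. Leaving out tumor 2, 4 or 5 gave 208, 177 and 204 passing genes.

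Among the lists tested, the 3 of neurons and oligodendrocytes held the largest shifts in tumor 1. None of the 3 calls was kept by camera with an estimated correlation, whose value is called camera adjusted p below. With so few arrays, that setting could hardly keep any call. The 6 measured genes of Purkinje cells and inhibitory neurons had a median difference of 3.27 on the log2 scale (percentile 100 of the random lists, camera adjusted p = 0.278), and 6 of 6 passed, both over all genes and adjusted over the list alone. Beside Calb1, Gad1 and Car8 they included Pcp4, a Purkinje cell calmodulin regulator, which was at least 10.4-fold higher. Calb1, Gad1 and Pcp4, with means of 4.83, 5.46 and 5.48 in the other 3 tumors, reached the filter of 5.87 through tumor 1 alone. Without tumor 1 this list kept 2 genes past the filter, that of mature neurons 7 and that of oligodendrocytes 6. Passing of genes let in this way is no separate support. The 10 genes of mature granule and other neurons had a median of 1.31 (percentile 100, camera adjusted p = 0.278), with 10 of 10 higher, 4 passing and 5 passing adjusted over the list alone. Among these, Chn2 was at least 8.45-fold and Syt1, a calcium sensor of synaptic vesicles, at least 4.90-fold higher. The 8 oligodendrocyte genes also had a median of 1.31 (percentile 100, camera adjusted p = 0.278): 5 were higher and 3 lower, 3 passed, and 5 passed adjusted over the list alone. Ugt8a, an enzyme of myelin lipid synthesis, was 4.73-fold higher, and Cldn11, a claudin of myelin, at least 4.10-fold. The 3 lower genes were Sox10 (5.67 in tumor 1), Olig1 (10.08) and Olig2 (7.49), transcription factors of the lineage that read higher in each other tumor.

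Smaller shifts in tumor 1 were seen in glial, stromal and imprinted genes, calls that were all lost with camera and an estimated correlation. The 16 genes of astrocytes and Bergmann glia had a median difference of 0.44 (percentile 100, camera adjusted p = 0.278), with 12 higher and 2 passing: Gdf10, a Bergmann glia marker, was 3.57-fold higher (adjusted p = 0.00813) and Gjb6, connexin 30 of astrocytes, 3.07-fold (adjusted p = 0.0472). The 8 imprinted genes had a median of 0.34 (percentile 99.8, camera adjusted p = 0.278), and Ndn, a neuronal growth suppressor, passed at 4.42-fold (adjusted p = 0.00264). The 9 genes of fibroblasts, meninges and mural cells had a median of 0.45 (percentile 99.9, camera adjusted p = 0.342), with 8 higher, 0 passing and 1 passing adjusted over the list alone. The pericyte gene Rgs5 led this list with a difference of 1.08 (adjusted p = 0.0503). That call was lost without tumor 2 (0.34), without tumor 4 (0.27) and with the mean in place of the median, and the imprinted call was lost without probe sets of an _x_at or _s_at suffix.

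Genes of dividing cells were lower in tumor 1 in the list test, each by less than 2-fold, but were not called by camera with an estimated correlation. In the G2 and M phase list, 23 of 23 genes were lower, with a median difference of -0.45 (percentile 0, camera adjusted p = 0.278), and in the S phase list 22 of 22, with a median of -0.41 (percentile 0, camera adjusted p = 0.278). No gene of either list passed on its own, over all genes or adjusted over the list alone (0 of 23 and 0 of 22). Aurka, a mitotic kinase, differed by -0.68 (adjusted p = 0.0801) and Mcm2, a subunit of the replicative helicase, by -0.76 (adjusted p = 0.110). The 19 genes of MYC and ribosome biogenesis were lower in 19 of 19 cases, with a median of -0.22 (percentile 0.21, camera adjusted p = 0.278), Polr1b leading at -0.63 (adjusted p = 0.171). Of the 14 SHH pathway genes, 12 were lower, with a median of -0.38 (percentile 0, camera adjusted p = 0.342) and 0 passing, and Atoh1 differed by -0.83 (adjusted p = 0.103) and Sfrp1 by -0.61 (adjusted p = 0.184). The ribosome biogenesis call was lost with the filter at the 75th percentile. These lists were lower in the same tumor in which the neuronal, oligodendrocyte and astrocyte lists were higher. The counts of lower members do not allow for a shift shared by genes of like signal. In tumor 1 the heat shock list, with a median of -0.037, stood at percentile 71.9, so most of its matched random lists lay lower still.

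The granule cell progenitor list was higher in tumor 1, with a median difference of 0.24 over 17 genes (percentile 100, camera adjusted p = 0.278) and 12 of 17 higher. The members that passed were Pax6, at 2.39-fold (adjusted p = 0.0317), and Cntn2, at 2.18-fold (adjusted p = 0.0283), an adhesion molecule of granule cells that have left the cell cycle. Nhlh1, also known from such cells, differed by 0.74 (adjusted p = 0.109), and Atoh1 by -0.83 (adjusted p = 0.103). Microglia and macrophage genes were lower in tumor 1, with a median of -0.34 (percentile 0, camera adjusted p = 0.540) and 14 of 17 lower. Ptprc, the leukocyte antigen CD45, at the floor in tumor 1, passed at -1.15 (adjusted p = 0.0429), and Lyz2, the macrophage lysozyme, read -1.19 (adjusted p = 0.0560), and these 2 passed adjusted over the list alone. The microglia call was lost without tumor 4 (-0.17).

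**Figure D1:**
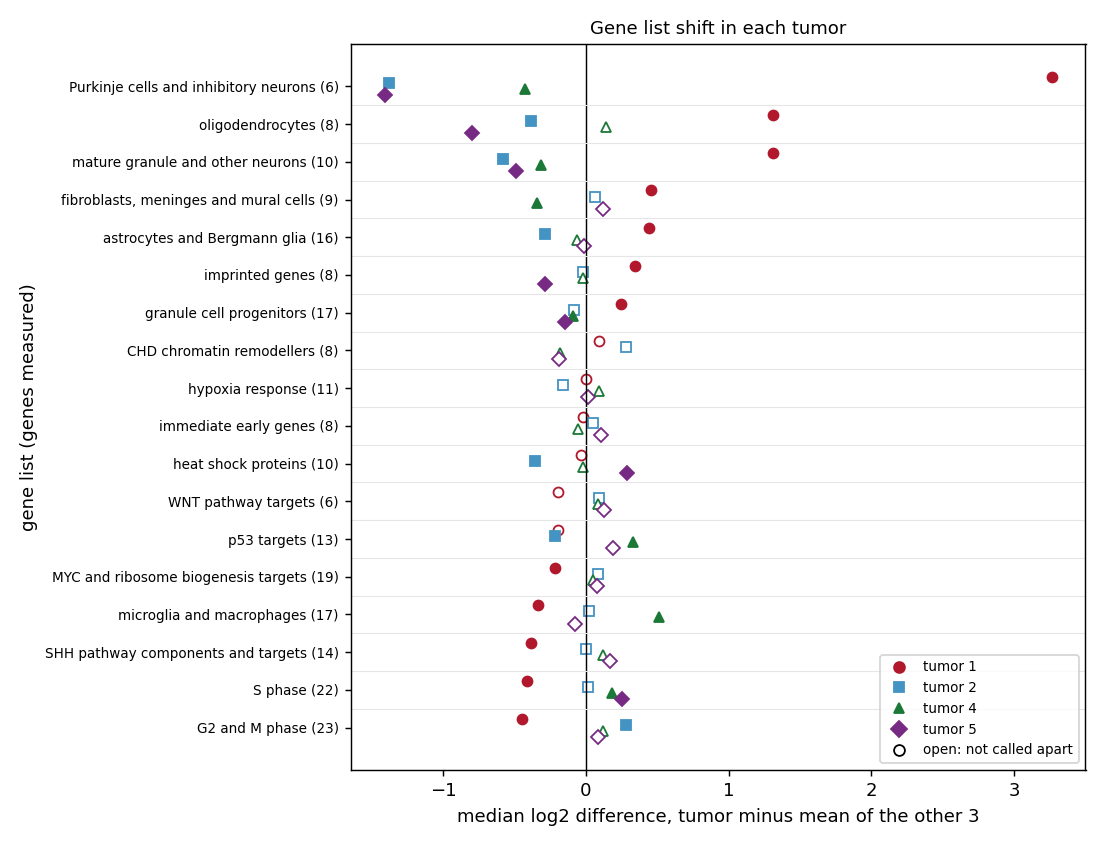
Median difference in log2 signal of each gene list in each tumor from the mean of the other 3 tumors (x axis), for the 18 lists with 5 or more measured genes (y axis, number of genes in parentheses). Filled symbols were called apart from matched random lists and open symbols were not, and camera with an estimated correlation called none. Tumor 1 reaches 3.27 for Purkinje cells and inhibitory neurons and lies at -0.45 for G2 and M phase.

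In tumor 2, mitotic genes were higher than in the other tumors, and p53 target and heat shock genes were lower, in the list test. With camera and an estimated correlation none of these calls was kept, and without tumor 1 the mitotic call was lost as well. In the G2 and M phase list 22 of 23 genes were higher, with a median difference of 0.28 (percentile 100), and Cenpf, a kinetochore protein gene, differed by 0.77 (adjusted p = 0.795) and Mki67 by 0.68 (adjusted p = 0.795). Of 10 heat shock genes, 9 were lower, with a median of -0.36 (percentile 0.02), and Cryab, the small heat shock protein αB-crystallin gene, differed by -0.65 (adjusted p = 0.795). Of 13 p53 targets, 11 were lower, with a median of -0.22 (percentile 0.47), and Phlda3 differed by -1.02 and Gadd45a by -0.86 (adjusted p = 0.795 for both). Lists of Purkinje cells (-1.38), mature neurons (-0.58), oligodendrocytes (-0.39) and astrocytes (-0.29) were also called lower, with a camera adjusted p of 0.931 for oligodendrocytes and 0.887 for the other 3. No gene of these lists passed, and 1 mature neuron gene passed adjusted over the list alone.

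These shifts include tumor 1 among the tumors set against tumor 2. Without tumor 1, the p53 list (-0.39, percentile 0) and the heat shock list (-0.35, percentile 0.31) stayed lower, and the calls of G2 and M phase (0.087, percentile 99.2), mature neurons, oligodendrocytes and astrocytes were lost. The Purkinje list then had 2 genes, too few to test, with a median of -0.0052. The p53 call was also lost without tumor 4 (-0.067), without tumor 5 (-0.18) and in 7 of 10 other settings, and the heat shock call in 4 of 10. No gene passed in tumor 2 in the limma test, 496 had an unadjusted p under 0.05, and the smallest adjusted p was 0.131, that of Ptgds, the prostaglandin D2 synthase gene, at -2.13 (SE 0.17). Among genes above the floor in all tumors, the next largest differences were Mbp at -1.77 and Mab21l2 at 1.56 (adjusted p = 0.795 for both). Set against tumors 4 and 5 alone, Ptgds differed by -2.05.

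In tumor 4, microglia and macrophage genes and p53 targets were higher than in the other tumors in the list test. Neither call was kept by camera with an estimated correlation. Of the 17 microglia genes 16 were higher, with a median difference of 0.51 (percentile 100). Lyz2 differed by 0.87, Ly86 by 0.66 and Trem2, a receptor of microglia, by 0.65 (adjusted p = 1.00 for each). Of 13 p53 targets 12 were higher, with a median of 0.33 (percentile 100): Cdkn1a, the cell cycle inhibitor p21, differed by 0.73, Aen by 0.71 and Phlda3 by 0.70. S phase genes were higher in 22 of 22 cases, with a median of 0.18 (percentile 99.8, camera adjusted p = 0.821), a call lost without tumor 1. Genes of fibroblasts, meninges and mural cells were lower, with a median of -0.34 (percentile 0.01, camera adjusted p = 0.821) and 7 of 9 lower, Igf2 leading at -1.13 (adjusted p = 1.00), and 1 gene of that list passed adjusted over the list alone. Lists of mature neurons (-0.32), Purkinje cells (-0.43) and granule cell progenitors (-0.091) were called lower as well (camera adjusted p = 0.821 for each). The Purkinje median is no bound, since Calb1 was raised to the floor in tumors 2 and 5: as measured it read 6.02 in tumor 4 and 5.98 as the mean of the other 3.

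Without tumor 1, the microglia list (0.44, percentile 100) and the p53 list (0.25, percentile 100) stayed higher in tumor 4, and 2 further lists were then called higher, interferon response (0.52, percentile 100), with 5 genes past the filter, and oligodendrocytes (0.21, percentile 99.7). The calls of S phase, granule cell progenitors, fibroblasts and mature neurons were lost, the last with a median of 0.082, the Purkinje list had 2 genes, too few to test, with a median of 0.58, and the call of progenitors was also lost without tumor 2. With the filter at the 75th percentile the p53 and S phase calls were lost, and with the floor at the 25th percentile that of Purkinje cells. In the limma test 0 genes passed in tumor 4, with 47 at an unadjusted p under 0.05. The largest differences among genes above the floor in all tumors were Lcn2 at 2.24, Clic6, a chloride channel gene, at -2.04 and Mtm1 at -1.64 (adjusted p = 1.00 for each). Set against tumors 2 and 5 alone, Clic6 differed by -1.63 and Mtm1 by -1.33.

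In tumor 5, heat shock and S phase genes were higher and oligodendrocyte genes lower in the list test. With camera and an estimated correlation none of these calls was kept, and without tumor 1 the S phase call was lost as well. Of 10 heat shock genes 10 were higher, with a median difference of 0.29 (percentile 99.7): Hspb1 differed by 0.70, Hsph1 by 0.53 and Hspe1 by 0.46 (adjusted p = 0.957 for each). Of 22 S phase genes 20 were higher, with a median of 0.25 (percentile 100), led by Gins2 at 0.45 and Pole2 at 0.44. Of 8 oligodendrocyte genes 6 were lower, with a median of -0.80 (percentile 0), and Mbp differed by -1.48, Ugt8a by -1.31 and Cldn11, at the floor in tumor 5, by -1.28. The 8 imprinted genes had a median of -0.29 (percentile 0.44, camera adjusted p = 0.735), with Plagl1 at -1.29. Lists of Purkinje cells (-1.41), mature neurons (-0.49) and granule cell progenitors (-0.15) were called lower too (camera adjusted p = 0.735 for each). No gene of these lists passed, over all genes or adjusted over the list alone.

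Without tumor 1, the heat shock list (0.42, percentile 100) stayed higher and the oligodendrocyte list (-0.59, percentile 0) stayed lower in tumor 5. The calls of S phase (0.087, percentile 78.2), imprinted genes (-0.20), mature neurons and granule cell progenitors were lost, the last with a median of 0.0025. The Purkinje list then had 2 genes, too few to test, with a median of -0.57. Called without tumor 1 but not with it were the microglia list, lower (-0.23, percentile 0.05), and the list of fibroblasts, meninges and mural cells, higher (0.28, percentile 99.7). The imprinted call was lost in 4 of 10 other settings and the heat shock call in 2 of 10. In the limma test 0 genes passed in tumor 5, with 306 at an unadjusted p under 0.05 and a smallest adjusted p of 0.957. Among genes above the floor in all tumors, the largest differences were Car8 at -1.80, the transporter gene Abca8a at 1.70 and Opcml at -1.64. Set against tumors 2 and 4 alone, Abca8a differed by 2.02.

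Of the 18 lists tested, 4 were called in no tumor: WNT targets, hypoxia response, immediate early genes and CHD remodellers. The 8 CHD genes had a median of 0.28 in tumor 2 (percentile 99.1) and of 0.092, -0.18 and -0.19 in tumors 1, 4 and 5. The WNT median was lowest in tumor 1, at -0.19 (percentile 7.23), that of hypoxia lowest in tumor 2, at -0.16 (percentile 5.88), and that of immediate early genes highest in tumor 5, at 0.11 (percentile 79.4). Another 5 lists had fewer than 5 measured genes. The 3 photoreceptor and group 3 or 4 genes had medians between -0.16 and 0.23, the 4 endothelial genes between -0.16 and 0.24, and the 4 interferon genes were highest in tumor 4 (0.49) and lowest in tumor 1 (-0.44). The single choroid plexus gene, Clic6, and the single ciliated cell gene are values without a test, the latter lowest in tumor 2 (-1.16) and highest in tumor 5 (0.84). No lymphocyte, erythroid or skeletal muscle gene passed the filter. Over the 72 comparisons of a list with a tumor, 33 were called, where 0.72 would be called by chance if genes were independent, and camera with an estimated correlation called 0.

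The genes with the largest SD over the 4 tumors, among those above the floor in each, were Lcn2 (2.05), Mbp (1.63), Car8 (1.63), Cadps2 (1.60), L1cam (1.52), Calb2 (1.42), Clic6 (1.35), Lrba (1.32), Sphkap (1.30) and Mab21l2 (1.27). Of these 10, 7 had their highest signal in tumor 1 and 3 (Lcn2, Lrba and Mab21l2) their lowest. Without tumor 1, 1 of the 10 was still in that list. Of 22 genes that were at the floor in at least 1 tumor and 4-fold or more above it in another, 17 were highest in tumor 1, among them Calb1 (9.45), Diras2 (9.32), Fam107a (9.19), Pcp4 (9.14) and Gad1. Without tumor 1 the number was 3. As groups, 10 of the 18 lists had a spread past the upper threshold of the random lists, with the largest SD of the mean deviation in Purkinje cells and inhibitory neurons (1.53), mature neurons (0.77) and oligodendrocytes (0.55). Without tumor 1 it was 5 lists.

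**Figure D2:**
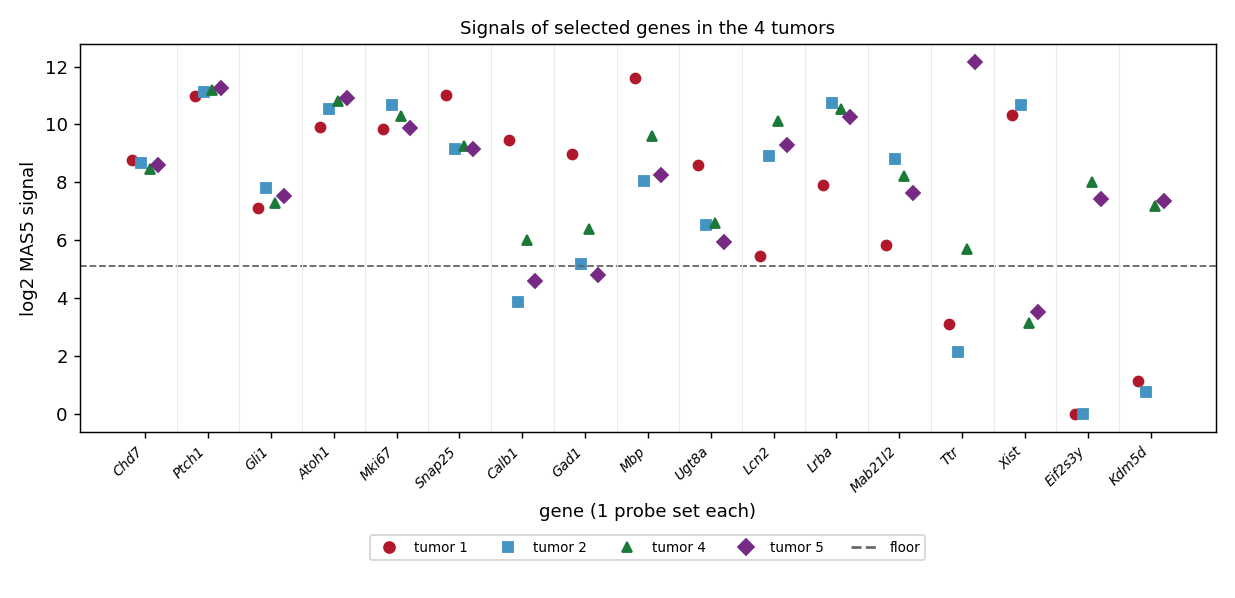
Log2 MAS5 signal (y axis) of 17 genes (x axis, 1 probe set each) in each of the 4 tumors, 1 point per tumor, with the floor of 5.12 as a dashed line. Calb1 and Gad1 are highest in tumor 1, Lcn2, Lrba and Mab21l2 are lowest there, and Xist is far above the floor in tumors 1 and 2 alone.

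Sex-linked transcripts split the tumors into pairs. Xist, the RNA of the inactive X chromosome, read 10.33 and 10.68 in tumors 1 and 2 and lay below the floor in tumors 4 and 5 (3.15 and 3.54). The Y-linked genes Eif2s3y (8.02 and 7.43), Kdm5d (7.18 and 7.35) and Uty (6.60 and 6.48) lay above the floor in tumors 4 and 5 and below it in tumors 1 and 2, where the highest of the 3 read 1.72. The labels give no sex. None of these 3 Y-linked genes reached the mean filter, so leaving sex-linked genes out took Xist alone from the genes tested. With Xist and the Y-linked genes left out, 121 genes passed in tumor 1 and 0 in each of the others.

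Genes with more than 1 probe set give the only repeat measurement on an array. Over 3321 such genes, the differences between tumors read by both probe sets correlated with Pearson's r between 0.50 and 0.77, across genes, which are not independent replicates. Of genes that differed by 2-fold or more, between 89.5% and 100% had the same direction in both. Over all 3321 genes it was between 62.4% and 75.9%. The lowest r was that of tumors 4 and 5, and the highest that of tumors 1 and 2.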

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

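Among the tests below, quantile normalization was planned before its result was seen, and the other tests were chosen after the result was seen.

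A tumor far from the other 3, by its gap to the nearest tumor against the whole range, was found in 12 of 106 named values, most of which were named for their large differences, so that their share is not set against chance. Over all 8498 genes it was found in 448 (5.27%), where chance gives about 1 in 20, with tumor 1 the outlying one in 194 and tumor 2 in 135. Tumor 1 lay apart in the log2 signals of Cadps2 (9.34), Snap25, a synaptic membrane protein (11.03), Ndn (9.84), Nhlh1 (7.91) and Gdf10 (7.46), which were higher there. It lay apart on the low side in Aurka (8.17), Lrba (7.90) and BC034090 (7.12), the last chosen after its values were seen. The mean deviation of the granule cell progenitor list lay apart in tumor 1 (0.16). Tumor 2 lay apart on the low side in Ptgds (6.88), in Gadd45a (6.22) and in the mean deviation of the hypoxia list (-0.10).

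A pattern in tumor 1, to which Snap25 and Gdf10 of these values belong, is that neuronal, oligodendrocyte and glial lists were called higher there together, calls that were lost with an estimated correlation (adjusted p = 0.278 for each of the 4 lists). Array scaling or a signal-dependent difference of array 1 is argued against. The mature neuron list kept a median of 1.34 after quantile normalization, still past the threshold. Quantile normalization keeps the order of signals on an array, so a difference of RNA preparation or labelling was not tested. The B1 repeat control read highest on array 1 (10.97). The microglia list went the other way (-0.34), which argues against a lower share of tumor cells that raises every other cell type alike. Its call was lost with an estimated correlation and, at -0.17, without tumor 4. A lower share that changes cell types unequally is not tested by this list. The list of fibroblasts, meninges and mural cells was higher in the same tumor (0.45). Maturation of the tumor's own granule lineage cells does not account for the higher genes of the oligodendrocyte list (1.31, with 3 of 8 genes lower). For the mature neuron list (1.31) it cannot be told apart from other neurons, since other cell types were higher in the same tumor. More normal cerebellar tissue in this sample cannot be told apart from a difference of the tumor itself, since the lower G2 and M phase list (-0.45) goes with both and no normal cerebellum was measured, and list members left out by the mean filter and high in tumor 1 were Gabra6 of mature granule cells (9.33, against 5.14 or less elsewhere), Pcp2 of Purkinje cells (512 on the linear scale, against 55.7 or less) and Mobp of myelin (8.66, against 4.69 or less), examples chosen after their values were seen. Of the 40 members of these lists past the filter, 34 lay above the floor in each of tumors 2, 4 and 5, and 0 of the 75 listed genes stood in another list, and a biological difference of the tumors themselves stays open, as the design names none to test.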

How the results depend on the processing

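Of the called list shifts, 372 values under alternatives other than camera kept direction and call, 39 kept the direction without the call and 2 turned, both without tumor 1: mature neurons in tumor 4 (-0.80 to 0.082 leaving out each tumor) and granule cell progenitors in tumor 5 (-0.23 to 0.0025). Camera with an estimated correlation, which kept none of the calls, is not in this tally. Settings in which a list had too few genes to test, such as the Purkinje list without tumor 1, are left out too. Of the named differences in tumor 1, 63 kept their call and 6 did not. The median number of genes that differed 2-fold between tumors was 158, and it was 246 with no filter on the mean, 42 with the filter at the 75th percentile and 85.5 with log2 of signal plus the floor value (37 to 224 leaving out each tumor). Passing genes in tumor 1 numbered 57 with the floor at the 50th percentile and 29 with the filter at the 75th (177 to 208 leaving out each tumor). With no filter, 1, 5 and 6 genes passed in tumors 2, 4 and 5, and with the 75th percentile filter 1 in tumor 2 (leaving out each tumor, 0 to 29, 1 to 7 and 1 to 47). Lists called in tumors 1, 2, 4 and 5 numbered 7, 3, 3 and 2 with the 75th percentile filter, where fewer genes are tested (10 to 12, 2 to 7, 4 to 9 and 4 to 10 leaving out each tumor). Camera called 13, 7, 5 and 9 lists with its preset correlation and 0, 0, 0 and 0 with an estimated correlation. Lists with a wide spread numbered 5 to 11 leaving out each tumor. Of the 10 most variable genes, 4 stayed with the floor at the 25th percentile, 6 at the 50th, 5 with the 75th percentile filter and 4 with log2 of signal plus the floor value (1 to 8 leaving out each tumor). Genes at the floor in some tumors numbered 5 with the floor at the 25th percentile, 54 with no filter and 0 with the 75th percentile filter (3 to 27), and the setting without a floor gives no such number. The mean of Chd7 was 8.75 with log2 of signal plus the floor value, which adds to every signal, and 7.88 as the mean of both probe sets (8.58 to 8.67). The median r between probe sets was 0.62 (0.57 to 0.73), with no value for the mean of all probe sets, and the lowest Xist signal was 3.15 to 3.54. Apart from the fewer genes and the added value named here, the cause was not tested. No paired analysis was possible because the labels give a single group. Values at or below the floor have no order. By the floor's definition they make up about 40% of each array, a share that measures neither background nor array quality.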

Other observations

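The chromosome 6 tests and the tests of the genes lower in tumor 1, and the values of lists without the mean filter, were chosen after the result was seen.

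Choroid plexus genes, nearly all left out by the mean filter, were highest in tumor 5. Of the 8 listed genes above the floor in any tumor, 7 had their highest signal there, and the list's median difference was 1.04. A gene above the floor in tumor 5 alone must be highest there, so this count describes the values and tests nothing. Ttr, the transthyretin of choroid plexus epithelium, read 12.16 in tumor 5, 5.70 in tumor 4 and 3.12 and 2.14 in tumors 1 and 2, and its other 3 probe sets were highest in tumor 5 as well (11.61, 12.49 and 11.92). The potassium channel gene Kcnj13 (6.17), Sostdc1 (6.67), Kcne2 (5.28), the folate receptor gene Folr1 (6.14) and Kl (5.22) lay above the floor in tumor 5 and below it in the other 3. These genes were chosen after their values were seen. Interferon and antigen presentation genes were highest in tumor 4 in 8 of 10 cases above the floor, with a median difference of 0.62, and so were 15 of 19 microglia genes. These counts too hold genes let in by any tumor above the floor and were not set against chance.

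Cdkn2a, the locus of the p16 and p19 tumor suppressors and chosen after its values were seen, lay above the floor in tumors 4 (7.58) and 5 (7.20) and below it in tumors 1 (2.77) and 2 (4.91), on its single probe set. The p53 target list had mean deviations of 0.24 and 0.22 in tumors 4 and 5 and -0.25 and -0.21 in tumors 1 and 2. By its median it was called apart in tumors 2 and 4 (adjusted p = 0.887 and 0.821 with an estimated correlation, which does not pass), not in tumor 1 (-0.20, percentile 1.5) or tumor 5 (0.19, percentile 98.1), and the tumor 2 call was lost in 7 of 10 other settings and the tumor 4 call with the filter at the 75th percentile. Among its members Cdkn1a read 8.04 and 8.07 in tumors 4 and 5 and 6.44 and 7.42 in tumors 1 and 2, and Aen 7.83 and 7.79 against 6.62 and 6.96. Xist and the Y-linked genes set apart the same pairs of tumors.

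Chromosome 6 genes also differed between these pairs. Over 425 genes, the median was higher in tumors 4 and 5 than in tumors 1 and 2 by 0.18 to 0.19 in the 4 pairs, with 68.7% to 74.1% of genes higher, while the largest median of any other of the 20 chromosomes was 0.097 in size. A signal-dependent difference between arrays is argued against, since the smallest of the 4 (0.18) lay above the highest of the matched random lists (0.12), and a few neighbouring genes are argued against, since each of 4 blocks of neighbouring genes was higher in each pair (0.14 or more). A gain of this chromosome in some or all cells of tumors 4 and 5 is a hypothesis that may be worth a test on DNA. Only differences between tumors were measured, without normal tissue, so a loss in tumors 1 and 2 cannot be told apart from it. If it is a gain, an extra copy in every cell cannot be told apart from a gain in part of the cells. The largest median (0.19) is below the log2 of 3/2 (0.58), but no known ratio on these arrays shows how far they compress differences.

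The 21 genes lower in tumor 1 had a median difference of -1.58. They included Lrba (-2.61) and its neighbour on the chromosome Mab21l2 (-2.36), Wnt4 (-2.12) and Cxcl5 (-1.68), of which Wnt4 and Cxcl5 were named after their values were seen. Ptprc of the microglia and macrophage list was among them (-1.15, at the floor in tumor 1), and that list was lower in the same tumor (-0.34). Dilution of tumor RNA by other tissue to the level of the G2 and M phase list (-0.45) is argued against as the whole cause of the set and stays open as a part of it: 406 genes lay below that level, so that it could hold about 812, of which at most 8.03 would be expected to pass, against the 21 seen, while 53.2 would pass if all 8498 genes sat there. Tested singly against the level of the G2 and M phase list, Lcn2 (-3.97), Lrba (-2.61) and BC034090 (-2.06) lay below it. The other genes of the set could not be told apart from it. The count treats genes as independent and speaks for the set, not for most of its members. A sequence variant under a single probe set, possible in mice of mixed background, is argued against for the 5 genes with another probe set above the floor, as 5 of 5 of those (100%) were lower too, with a median of -1.79. For the other 16 genes it cannot be told apart from lower expression, since no other probe set above the floor was there to test.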
